A study of Homo sapiens with 9 samples.

How the data were processed

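RNA of MCF10A cells was hybridised to 9 Affymetrix arrays of 54675 probe sets, 3 each for empty vector, ERBB2 retrovirus and empty vector with EGF. Cells were maintained with 5% horse serum and 20 ng/ml EGF and assayed with 2% serum without EGF, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes, and its version and settings are not given in the sources used here. The mean after trimming 2% of probe sets at each end was 100.03 on all 9 arrays, from which array-wise scaling by the authors was read. MAS5 subtracts background and scales each array as a whole, so a shift of many genes one way is partly absorbed. Detection calls were not used here, so it is unknown which low signals exceed background. Between 44.1% and 50.6% of probe sets read under 16 on each array.

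The platform's annotation named 1 gene for 41097 probe sets, several for 1801 and none for 11777. Of the first, 41043 had an Entrez number in the RefSeq gene table, and no symbol needed updating. Probe sets with several genes were tested but not named. Of 426 different genes in the lists, 350 had a probe set past the filter and 39 were named by no single-gene probe set. No probe positions were given, so no genome coordinates are reported. Groups and replicate numbers came from the sample titles.

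Values were analysed as log2(signal + 16), so that fold changes of dim genes are understated. The 62 Affymetrix control probe sets were left out, and probe sets with a mean above the 40th percentile were kept, which left 32769 probe sets and 13726 genes. A gene was represented by its probe set with the highest mean. The 3 comparisons were tested with limma 3.58.1 (lmFit and eBayes with a variance trend) in R 4.3.3, in 1 model of group means over all 9 arrays with 6 residual degrees of freedom, and Benjamini-Hochberg adjusted p-values under 0.05 were called. A single gene tested alone with 3 against 3 arrays could not reach an exact permutation p under 0.1. The 24 gene lists, the rule for the genes named and the alternatives were fixed before the data were examined. The lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. Errors in the text are SDs of signals or SEs of log2 changes. Shared controls were addressed with 50 simulations of unchanged groups.

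The rule for the genes named took, per comparison, the 10 largest called rises and 10 largest called falls with groups that did not overlap and a higher-group mean above the median, up to 4 called members per list or else the 2 with the largest change, 5 genes for each kind of overlap, and EGFR, ERBB2, ERBB3, ERBB4, FOS, EGR1, MYC and DUSP6. The alternatives tried were pseudocounts of 1 and 64, no filter and the 60th percentile, quantile normalization, equal array medians, eBayes without trend, array weights, only the arrays of the groups compared, the replicate number as a block, leaving out each array, 1 probe set per gene and other ways to test lists.

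Data were simulated with independent normal noise from these arrays' means and spreads, with known changes in a small part of the probe sets. There, 67.4% of 2-fold changes were recovered in the comparison of ERBB2 with vector over 32770 probe sets. The shares were 71.1% in EGF with vector over 32767 and 64.1% in ERBB2 with EGF over 32769. For 1.5-fold changes the shares were 38.0%, 31.1% and 28.0%. Of the calls made, 8 of 135, 7 of 128 and 5 of 119 were false. In the data 12689, 9445 and 7792 probe sets were called, so the adjusted threshold was stricter in the simulation. These shares and false calls therefore do not carry over to the data.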

Results

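MCF10A, an immortalized, non-tumorigenic human mammary epithelial line whose growth depends on added EGF, was profiled on 9 one-colour Affymetrix expression arrays. The arrays formed 3 groups of 3 biological replicates. The vector group carried an empty pBabe retrovirus, the ERBB2 group a pBabe retrovirus for the receptor tyrosine kinase ERBB2, and the EGF group the empty virus with EGF added at 50 ng/ml for 2 h before harvest. After infection all cells were held in medium with 2% horse serum and without EGF. The labels call the replicates biological and do not say whether they came from separate infections, so p-values measure the spread between these samples. Median signals on the authors' linear scale lay between 15.6 and 16.9 on EGF arrays and between 17.9 and 20.1 on arrays labelled ERBB2. On vector arrays they lay between 19.85 and 20.2, so the medians of the EGF arrays were the lowest. The number of arrays limits the precision. The most similar array was one of the same group for 9 of 9 arrays. Correlations of log2 values lay between 0.971 and 0.982 within groups and between 0.912 and 0.957 across groups.

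The transcript that defines the ERBB2 group was examined first. The brightest ERBB2 probe set was not higher in the arrays labelled ERBB2: its signal was 174.0 ± 48.0 (SD, n = 3) in vector cells, 98.8 ± 23.1 in cells labelled ERBB2 and 104.1 ± 23.3 with EGF. The log2 change in the arrays labelled ERBB2 was -0.71 ± 0.20 (SE, limma adjusted p = 0.006757). That call ended without vector replicate 2 (log2 change -0.553, adjusted p = 0.05061) or without ERBB2 replicate 2 (-0.535, adjusted p = 0.05174), and over 19 alternatives its adjusted p lay between 0.001085 and 0.05174. A dimmer probe set rose from 12.6 ± 8.78 to 35.6 ± 2.51 (log2 change 0.89, adjusted p = 0.008823), and the remaining one differed by 0.10 (adjusted p = 0.8236). The sources used here do not give the species or extent of the introduced sequence or the positions of the probes, so these probe sets do not settle the label, and the group is called "labelled ERBB2" throughout. EGFR, the EGF receptor, fell from 1835 ± 153 to 975.3 ± 143 in the arrays labelled ERBB2 (log2 change -0.91, adjusted p = 2.696e-07). With EGF it was at 1873 ± 144 (0.03, adjusted p = 0.8556). Its 6 other probe sets past the filter all had negative changes with EGF, and 2 were called. These 2 changed by -0.23 (adjusted p = 0.03824) and -0.50 (adjusted p = 0.0005451), the first from a mean signal of 2018 to 1720. ERBB3, the kinase-impaired family member, fell with EGF from 114.0 ± 17.6 to 32.3 ± 10.1 (-1.44, adjusted p = 6.814e-06). In the arrays labelled ERBB2 it stood at 67.3 ± 5.88 (-0.64, adjusted p = 0.0106), a call that ended without vector replicate 1 (-0.532, adjusted p = 0.06138, with 0.004187 the lowest over 19 alternatives). None of the 3 other ERBB3 probe sets past the filter was called there, and their changes were -0.38, 0.39 and 0.50. No ERBB4 probe set passed the filter on low values.

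**Figure D1:**
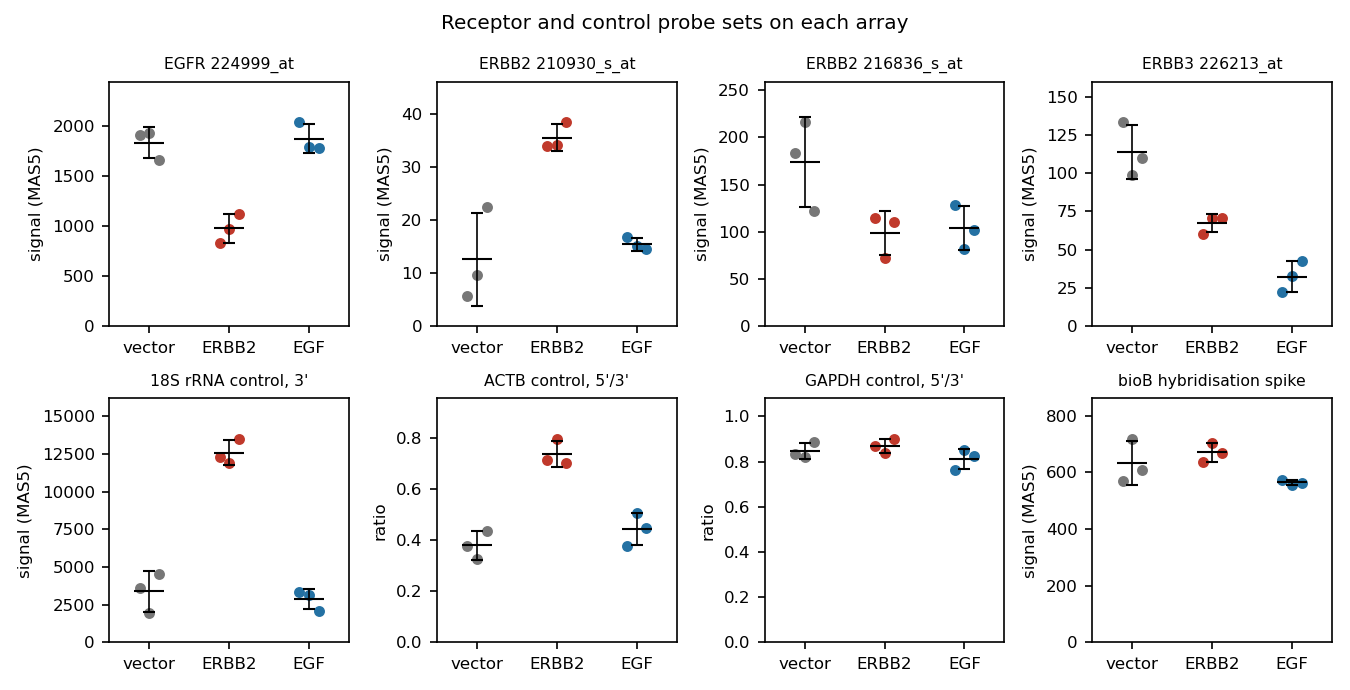
Signal (linear MAS5 units) or signal ratio on each of the 9 arrays for receptor probe sets (upper panels) and chip control probe sets (lower panels), by group, where each point is an array and the bar shows the mean with its SD (n = 3). The brightest ERBB2 probe set averaged 98.8 in the arrays labelled ERBB2 against 174.0 in vector arrays, and the ACTB 5'/3' ratio averaged 0.737 against 0.379.

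Control probe sets also set the arrays labelled ERBB2 apart. The ratio of the 5' to the 3' ACTB control was 0.737 ± 0.051 there, 0.379 ± 0.055 in vector arrays and 0.444 ± 0.063 with EGF. The 3' control for 18S ribosomal RNA read 12587 ± 826 against 3380 ± 1330 and 2868 ± 673, and its 5' control 15873 ± 833 against 13312 ± 1514 and 9266 ± 812. The GAPDH 5'/3' ratios were 0.869 ± 0.032, 0.847 ± 0.034 and 0.812 ± 0.045. These control differences run with the group and therefore accompany every gene group described below for the arrays labelled ERBB2.

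The first comparison asked how the arrays labelled ERBB2 differed from the vector arrays, both without EGF. Genes of the cell cycle, of ribosome biogenesis and of ERK output were higher in the arrays labelled ERBB2, and FOXO and growth factor withdrawal genes and mesenchymal genes were lower. DUSP6, a phosphatase that limits ERK, went from 9.42 ± 7.51 to 963 ± 233 (SD, n = 3; log2 change 5.29 ± 0.18 SE, adjusted p = 1.36e-14). SELENOP, a secreted selenoprotein, went from 4855 ± 186 to 74.6 ± 6.11 (-5.75 ± 0.08, adjusted p = 5.248e-20). Of 32769 probe sets tested, 5798 rose and 6891 fell at an adjusted p under 0.05, or 38.7%, and 3631 of these changed by at least 2-fold. The median change of all probe sets was -0.07. Counted by the probe set that represents each gene, with p-values still adjusted over all probe sets, 2855 of 13726 genes rose and 3425 fell.

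Among the largest rises were also ANGPTL4 (log2 change 3.94), ALDH1A3, a retinaldehyde dehydrogenase (3.80), DTL (3.83) and FEN1 (3.39), both of DNA replication, TNFRSF12A, the TWEAK receptor (3.43), AMIGO2 (3.57), the actin-bundling LCP1 (3.36) and the ERK-responsive factor ETV5 (3.35). The long noncoding RNA VHRT read 510.2 ± 71.5 in the arrays labelled ERBB2 against 1.08 ± 0.42 in vector arrays and 0.997 ± 0.784 with EGF, and without detection calls it is unknown whether the low values exceed background. Besides SELENOP, the largest falls were in MAOA, monoamine oxidase A (-4.78), the ubiquitin ligase subunit FBXO32 (-4.71), the estrogen sulfotransferase SULT1E1 (-4.59), GREB1 (-4.30), the keratin KRT15 (-4.27), FLRT3 (-4.12), the glucocorticoid-induced TSC22D3 (-4.06), the epithelial factor EHF (-4.03) and the antiproliferative BTG1 (-4.02). The rule for the genes named required a call and groups that did not overlap, so neither is a finding about these 20 genes. Each had an adjusted p of at most 4.438e-11, and every further probe set of these genes past the filter had the same sign. Groups did not overlap for 47.0% of all probe sets, against 10% by chance.

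Of 24 gene lists, 13 were called (camera, adjusted p under 0.05), 7 higher and 6 lower. All 32 measured cell cycle genes rose, with a median log2 change of 1.98 (adjusted p = 1.507e-23, and 0.02961 with an estimated correlation), among them the replication factors CDC45 (3.12), CDC6 (2.82) and MCM6 (2.81) and cyclin CCNE2 (2.95). The 3' control of 18S and the ACTB 5'/3' ratio moved with the same arrays. Of 16 ribosome biogenesis and MYC target genes, 15 rose and 1 fell (median 1.31; adjusted p = 7.447e-11, 0.02553 with an estimated correlation), for example PNO1 (2.06) and RRS1 (1.78). ERK feedback and output genes rose in 16 of 21 cases and fell in 2 (median 1.19; adjusted p = 6.133e-06, 0.02961 with an estimated correlation), with CCND1, cyclin D1 (2.73), and the inhibitor SPRY4 (2.54). Cholesterol synthesis genes rose in 13 of 18 and fell in 2 (adjusted p = 1.927e-05, 0.042 with an estimated correlation), led by HMGCS1 (2.38), while 1 of 3 further probe sets of IDI1, another member at 1.37, was called the other way. FOXO and growth factor withdrawal genes fell in 17 of 19 with none rising (median -2.04; adjusted p = 7.186e-13, 0.004363 with an estimated correlation), with TXNIP (-3.57), the pyruvate dehydrogenase kinase PDK4 (-3.39) and YPEL3 (-3.11). Mesenchymal genes fell in 10 of 15 and rose in 1 (adjusted p = 0.002596, 0.04565 with an estimated correlation), including the transcription factors TWIST1 (-2.19) and SNAI2 (-2.01). For these 6 lists the counts adjusted over the list alone were the same.

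The other 7 called lists lost their call with an estimated correlation. Immediate early genes rose in 11 of 23 and fell in 4, or 12 and 5 adjusted over the list alone (adjusted p = 0.01498, and adjusted p = 0.07013 with an estimated correlation). EGR1 rose from 144.8 ± 15.95 to 1009 ± 163 (2.67) and CCN2 by 2.99, whereas FOS fell from 274.6 ± 47.1 to 116.7 ± 21.7 (-1.13, adjusted p = 1.095e-06). MYC differed by 0.27 (adjusted p = 0.01565), and its call ended without vector replicate 1 (log2 change 0.244), vector replicate 3 (0.25) or ERBB2 replicate 1 (0.17), without the filter and without a variance trend, with adjusted p between 0.000242 and 0.1418 over 19 alternatives. Basal epithelial genes fell in 6 of 9 and rose in 1 (adjusted p = 0.0003699, adjusted p = 0.0817 with an estimated correlation), with KRT14 at -4.00 and KRT5 at -0.93. The p53 targets and cyclin kinase inhibitors fell in 7 of 13 and rose in 2 (adjusted p = 0.004834, adjusted p = 0.05493 with an estimated correlation), led by CDKN1C (-2.97). Interferon response genes fell in 11 of 26 and rose in 1 (adjusted p = 0.03503, adjusted p = 0.1196 with an estimated correlation, 0.06563 without ERBB2 replicate 3 and 0.07349 with the filter at the 60th percentile), with IFI44L at -2.72. Fatty acid synthesis genes rose in 7 of 10 with none falling (adjusted p = 0.01498, adjusted p = 0.1678 with an estimated correlation), and actin cytoskeleton and SRF target genes rose in 7 of 11 and fell in 2 (adjusted p = 0.01809, adjusted p = 0.1678 with an estimated correlation). Genes of delayed early RNA decay and transcription repression fell in 10 of 17 and rose in 3 (adjusted p = 0.04902, adjusted p = 0.2436 with an estimated correlation). That last call also ended without any of 5 arrays, namely vector replicate 1 (adjusted p = 0.05378), ERBB2 replicate 2 (0.05571), ERBB2 replicate 3 (0.05731), EGF replicate 1 (0.05318) and EGF replicate 2 (0.05092), with a pseudocount of 1, with the filter at the 60th percentile and with the mean of all probe sets of a gene. Adjusted over the list alone, counts in these 7 lists differed only for the immediate early genes.

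Further lists were not called in this comparison, though single members changed. Keratinocyte differentiation genes fell in 10 of 16 and rose in 2 (adjusted p = 0.1075), the calcium-binding S100A9 rising by 2.81 and KRT13 at -1.51. Amino acid and unfolded protein response genes rose in 8 of 18 and fell in 7 (adjusted p = 0.1281), with asparagine synthetase ASNS up by 3.19. Luminal epithelial genes rose in 3 of 12 and fell in 6 (adjusted p = 0.245), glycolysis and hypoxia genes rose in 7 of 21 and fell in 7 (adjusted p = 0.7721), cytokine and NF-kB response genes rose in 6 of 15 and fell in 3 (adjusted p = 0.1943), extracellular protease and adhesion genes rose in 5 of 13 and fell in 6 (adjusted p = 0.5785) and heat shock genes rose in 6 of 9 and fell in 2 (adjusted p = 0.1527). Of 7 EGF family ligands HBEGF was called (0.47, adjusted p = 0.04143) and none was when adjusted over the list alone (list adjusted p = 0.494); that call ended under 12 of 19 alternatives, with adjusted p between 0.00567 and 0.1543, including leaving out vector replicate 1 or 3, any ERBB2 replicate or any EGF replicate. In the same comparison the list of ERBB receptors was not called (adjusted p = 0.08289), the brightest probe sets of its 3 measured genes being called lower but no other probe set of ERBB2 or ERBB3, and 1 of ERBB2 being called higher. Fibroblast markers rose in 1 of 4 and fell in 1 (adjusted p = 0.7995), as did blood and endothelial cell markers (adjusted p = 0.9925). Adjusted over the list alone, 7 luminal, 8 glycolysis and hypoxia and 11 keratinocyte differentiation genes fell. For 3 of these lists the median and the direction of the test differed in sign, with medians of 0.21 for the protease, -0.03 for the glycolysis and -0.19 for the blood and endothelial list.

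**Figure D2:**
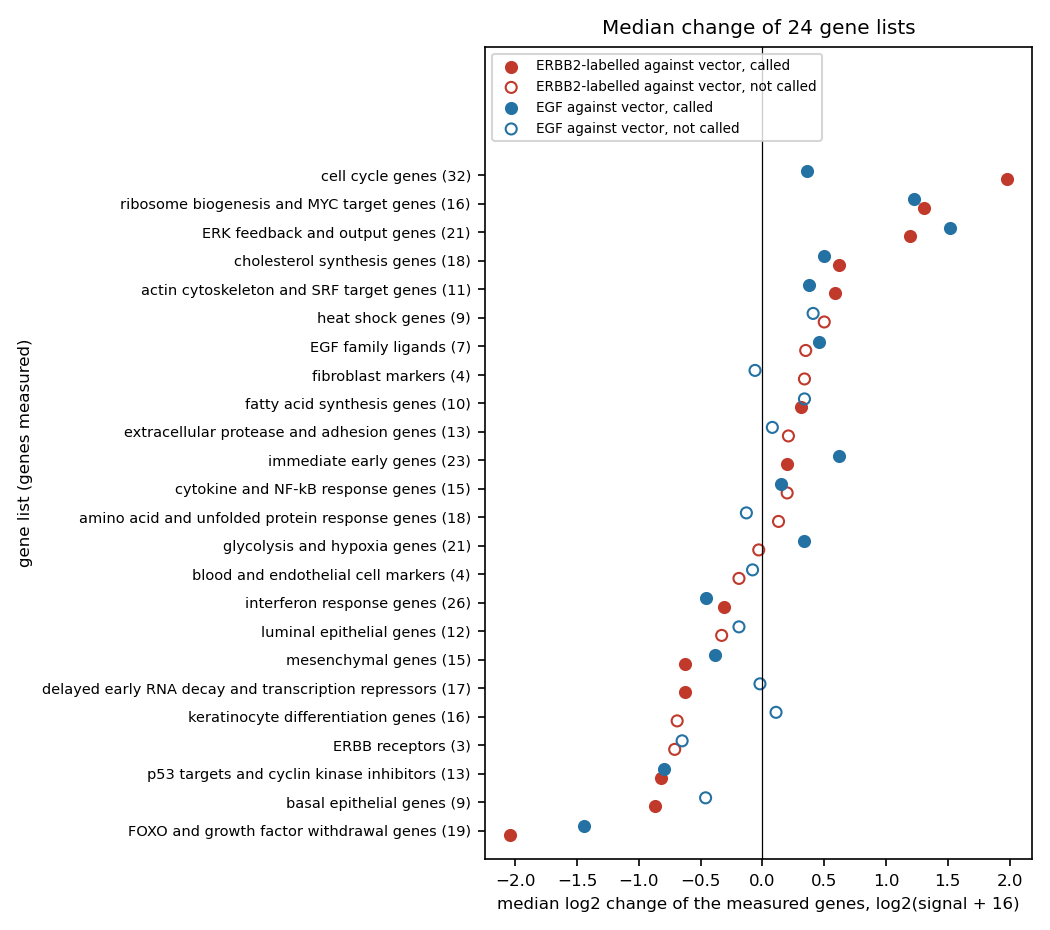
Median log2 change (horizontal axis, log2 of signal plus 16) of the measured genes of 24 lists in the arrays labelled ERBB2 and in the EGF arrays, each against vector, with filled points for the 13 lists called in each at an adjusted p under 0.05, of which 6 kept the call with an estimated correlation. The cell cycle list lay at 1.98 in the arrays labelled ERBB2 and at 0.36 with EGF (adjusted p = 0.2098 with an estimated correlation), and the FOXO list at -2.04 and -1.44.

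The second comparison asked what 2 h of EGF changed in vector cells. Immediate early genes, ERK feedback genes, ribosome biogenesis genes and genes of glycolysis and hypoxia rose, and FOXO and growth factor withdrawal genes fell. DUSP6 rose from 9.42 ± 7.51 to 2789 ± 219 (SD, n = 3; log2 change 6.83 ± 0.18 SE, adjusted p = 1.11e-15), EGR1 from 144.8 ± 15.95 to 2174 ± 35.6 (3.77) and FOS from 274.6 ± 47.1 to 569.8 ± 47.4 (1.02). The size of the DUSP6 change again depends on the 16 added to the signal. FBXO32 fell from 1034 ± 70.1 to 39.4 ± 1.98 (-4.24 ± 0.17, adjusted p = 6.26e-13). In all, 4234 probe sets rose and 5211 fell, or 28.8%, with 1699 changed by at least 2-fold, and 2357 genes rose and 2595 fell. The median change of all probe sets was -0.11. With equal array medians it became 0.05, a shift of over 0.1, and the share of rises among calls went from 44.8% to 67.5%, with 2885 falls, so small changes in this comparison are relative to the authors' scaling.

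Other large rises were in ANGPTL4 (5.28), the connexin GJB2 (4.48), AMIGO2 (3.76), the chemokine CCL20 (3.53), tissue factor F3 (3.44), PHLDA1 (3.36), xanthine dehydrogenase XDH (3.34) and the activin subunit INHBA (3.29). Large falls were in TNFSF11, the RANK ligand (-3.24), PCDH9 (-3.21), the chemokine receptor CXCR4 (-3.17), PDK4 (-3.0), GREB1 (-2.83), TSC22D3 (-2.77), VAV3 (-2.59), RAB30 (-2.56) and FIBIN (-2.50). Groups did not overlap for 42.2% of all probe sets, against 10% by chance.

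Of the 24 lists, 13 were called with EGF, 9 higher and 4 lower, and 6 of them kept the call with an estimated correlation. Immediate early genes rose in 15 of 23 with none falling (median 0.62; adjusted p = 1.245e-09, 0.004987 with an estimated correlation), including IER3 (2.77) and FOSL1 (1.82). ERK feedback and output genes rose in 15 of 21 and fell in 1 (median 1.52; adjusted p = 4.653e-10, 0.006586 with an estimated correlation), including SPRY4 (3.11), CCND1 (3.0) and DUSP4 (2.32). Ribosome biogenesis and MYC target genes rose in 15 of 16, or rose in 15 and fell in 1 adjusted over the list alone (median 1.23; adjusted p = 2.936e-15, 0.006215 with an estimated correlation), led by RRS1 (2.21), and MYC itself rose by 0.62. FOXO and growth factor withdrawal genes fell in 18 of 19 (median -1.44; adjusted p = 5.004e-13, 0.004213 with an estimated correlation), including BTG1 (-2.17) and the repressor BCL6 (-2.03). Glycolysis and hypoxia genes rose in 13 of 21 and fell in 2, or 15 and 2 adjusted over the list alone (adjusted p = 9.206e-07, 0.03714 with an estimated correlation), with hexokinase HK2 (2.00), VEGFA (1.84) and PDK1 (1.77). Cholesterol synthesis genes rose in 12 of 18 and fell in 3, or 13 and 4 adjusted over the list alone (adjusted p = 2.151e-05, 0.03714 with an estimated correlation), with HMGCS1 at 2.33. IDI1, of the same list, was at 0.90, and 2 of its 3 further probe sets were called the other way.

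The remaining 7 calls were lost with an estimated correlation. Cell cycle genes rose in 16 of 32 and fell in 1, or 17 and 1 adjusted over the list alone (median 0.36; adjusted p = 3.445e-05, adjusted p = 0.2098 with an estimated correlation), with CCNE2 at 1.96 and MCM6 at 1.67. Of 7 EGF family ligands 3 rose, HBEGF (2.24), EREG (2.14) and TGFA (0.85), of whose 2 further probe sets 1 had the other sign (adjusted p = 0.01193, adjusted p = 0.1053 with an estimated correlation). Cytokine and NF-kB response genes rose in 5 of 15 and fell in 1, or 6 and 1 adjusted over the list alone (adjusted p = 0.02356, adjusted p = 0.1053 with an estimated correlation), CXCL8 by 2.45. Actin cytoskeleton and SRF target genes rose in 6 of 11 and fell in 2 (adjusted p = 0.02146, adjusted p = 0.1737 with an estimated correlation). The p53 targets and cyclin kinase inhibitors fell in 8 of 13 and rose in 2, or 9 and 2 adjusted over the list alone (adjusted p = 0.004244, adjusted p = 0.05228 with an estimated correlation), with CDKN1A, which encodes p21, at -1.95. Interferon response genes fell in 14 of 26 and rose in 1, or 15 and 2 adjusted over the list alone (adjusted p = 0.008733, adjusted p = 0.06913 with an estimated correlation). Mesenchymal genes fell in 6 of 15 and rose in 1, or 7 and 1 adjusted over the list alone (adjusted p = 0.03573, adjusted p = 0.1053 with an estimated correlation), a call that also ended without vector replicate 1 (adjusted p = 0.06067) or EGF replicate 1 (0.05482). Basal epithelial genes fell in 7 of 9 and rose in 2 without a list call (adjusted p = 0.05718), with KRT15 at -0.73 while the laminin-binding integrin ITGA6 rose by 1.27.

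The third comparison tested directly where the arrays labelled ERBB2 and the EGF arrays differed. The groups differed in the retrovirus and in 2 h of EGF, so the kind of stimulus and its duration cannot be told apart. Cell cycle genes were higher in the arrays labelled ERBB2, and glycolysis and hypoxia genes and FOXO and growth factor withdrawal genes were lower than with EGF. KRT15 read 650.8 ± 49.2 in the arrays labelled ERBB2 and 7747 ± 397 with EGF (log2 difference -3.54 ± 0.07 SE, adjusted p = 7.904e-18), and the xenobiotic-metabolizing CYP1B1 read 2399 ± 15.4 and 200.8 ± 18.6 (3.48 ± 0.09, adjusted p = 7.566e-16). In total 3799 probe sets were higher and 3993 lower, or 23.8%, and 1398 differed by at least 2-fold. With equal array medians the share of higher calls went from 48.8% to 31.8% and the median difference of all probe sets from 0.03 to -0.08. The 3' control of 18S and the ACTB 5'/3' ratio differed between the same groups.

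Higher in the arrays labelled ERBB2 were also VHRT (4.94), LCP1 (4.16), PGBD5 (3.08), ASNS (2.82), PKIB (2.51), the sulfate transporter SLC26A2 (2.42), IGFL1 (2.42), the protease FAP (2.37) and SMOC1 (2.31). Lower were SELENOP (-4.36), FGFR3 (-3.80), NDRG1 (-3.69), SULT1E1 (-3.56), KRT14 (-3.43), IGFBP6 (-3.41), GJB2 (-3.13), glutamine synthetase GLUL (-2.97) and SELENBP1 (-2.79). Of 2 further SELENOP probe sets 1 had the other sign. Of the lists, 7 were called. All 32 cell cycle genes were higher (median 1.42; adjusted p = 1.205e-29, 0.03142 with an estimated correlation), with the mitotic genes PLK1 (2.15), CDC20 (2.08) and BUB1B (1.94). Glycolysis and hypoxia genes were lower in 15 of 21 and higher in 1, or 17 and 1 adjusted over the list alone (adjusted p = 1.201e-08, 0.03142 with an estimated correlation), with HK2 at -1.53, of whose 2 further probe sets 1 had the other sign, and BNIP3 at -1.49. FOXO and growth factor withdrawal genes were lower in 11 of 19 and higher in 1, or 14 and 1 adjusted over the list alone (adjusted p = 1.409e-06, 0.03092 with an estimated correlation). The calls of 4 lists were lost with an estimated correlation. Immediate early genes were lower in 11 of 23 and higher in 2, or 12 and 2 adjusted over the list alone (adjusted p = 0.003021, adjusted p = 0.05904 with an estimated correlation), with FOS at -2.15, EGR1 at -1.11 and CCN2 at 1.94. Basal epithelial genes were lower in 7 of 9 and higher in 1 (adjusted p = 1.054e-05, adjusted p = 0.0663 with an estimated correlation). Delayed early genes were lower in 11 of 17 and higher in 1, or 11 and 3 adjusted over the list alone (adjusted p = 0.0003512, adjusted p = 0.105 with an estimated correlation). Extracellular protease and adhesion genes were lower in 6 of 13, or 7 with 1 higher adjusted over the list alone (adjusted p = 0.01659, adjusted p = 0.1967 with an estimated correlation), with the inhibitor TIMP3 at -2.74. Without the filter on low values that list's median was 0.061 and its call ended (adjusted p = 0.07941).

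The responses to both treatments overlapped. Both comparisons called 6961 probe sets, of which 3012 rose in both, 3660 fell in both and 289 changed in opposite directions. Independent lists of the same sizes would share 749.1 rises and 1096 falls. Unchanged groups simulated against a common control, itself simulated, shared on average 0.02 probe sets. That value leaves out the effects and does not show how much of the overlap comes from the shared arrays. Log2 changes correlated across probe sets, which are not independent replicates, with Pearson's r 0.699 against 0.500 simulated and Spearman's rho 0.663, and their covariance was 0.241 against 0.0243. A split of the 3 control arrays would leave 1 part with a single array and was not made. Part of the excess in shared calls may therefore come from sharing them. The covariance minus its simulated value was 0.217, where the simulation covers only independent noise within groups. DUSP6, ANGPTL4, AMIGO2, F3 and XDH led the shared rises by the smaller of their 2 changes, and FBXO32, PCDH9, CXCR4, PDK4 and TNFSF11 the shared falls. Of the probe sets that changed the same way, 2251 also differed in the direct test, 1815 with the larger change in the arrays labelled ERBB2 and 436 with the larger change with EGF. The 289 that moved in opposite directions were also called in that test, which is close to fixed by their selection, since the direct difference adds both changes. They were led by SEMA6A, MIR210HG, STC1, NDRG1 and FOS, each lower in the arrays labelled ERBB2 and higher with EGF than in vector arrays. The rise of SEMA6A with EGF was not called with a pseudocount of 1 (adjusted p = 0.06446, against 0.0002606 as the lowest over 19 alternatives).

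**Figure D3:**
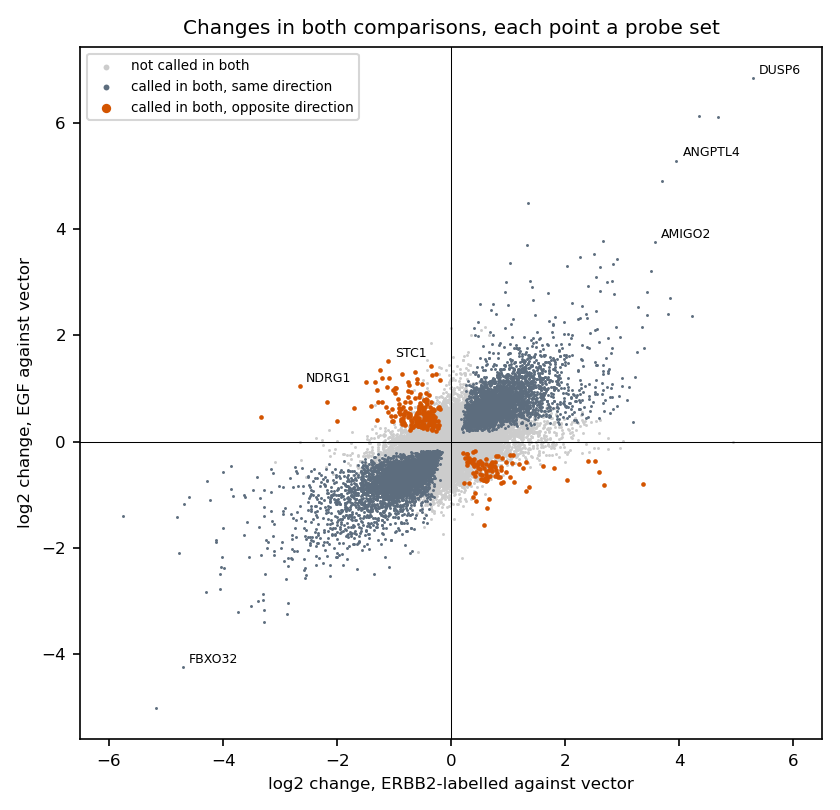
Log2 change of each of the 32769 probe sets tested in the arrays labelled ERBB2 (horizontal axis) and with EGF (vertical axis), each against vector arrays, coloured by whether both comparisons called it and in which directions. The 3012 probe sets called up in both and the 3660 called down in both lie along the rising diagonal, and the 289 called in opposite directions lie off it.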

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

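The explanations for the ERBB2 and control probe sets, except the cell cycle test and the splits of the arrays, were tested only after their results were seen.

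Genes whose changes went in opposite directions drew attention because the direct test found a difference between the responses. The arrays labelled ERBB2 minus the EGF arrays gave -3.69 for NDRG1, -2.61 for STC1, -2.61 for SEMA6A, -2.46 for MIR210HG and -2.15 for FOS on the log2 scale, with the highest adjusted p at 3.801e-07. These genes were selected for changes in opposite directions against vector, so these differences describe them and are no independent test.

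The ERBB2 probe set was not higher in the arrays labelled ERBB2. An exchange of single arrays between groups is argued against by the grouping, since 9 of 9 arrays were most similar to an array of their own group. Of 3 ERBB2 probe sets tested, 1 was called higher, so probe sets outside the introduced sequence, or matching another species' ERBB2 poorly, could explain the others, and without the insert and the probe positions this stays open. An exchange of the vector and ERBB2 labels as a whole also stays open. Lists higher in the arrays labelled ERBB2 were ERK feedback and output (median 1.19), ribosome biogenesis (1.31) and cell cycle (1.98). The FOXO list was lower (-2.04), and each of these lists moved in the direction seen with EGF. With EGF the cell cycle call was lost with an estimated correlation (camera, adjusted p = 0.2098). The glycolysis and hypoxia list was called with EGF only. Both directions are taken against the vector arrays, whose label is in question, so they cannot decide on an exchange. After an exchange the cell cycle and FOXO lists would still move alike in both responses. Their medians in ERBB2 against EGF were 1.42 and -0.55. The ERK and ribosome lists were not called there (camera, adjusted p = 0.1344 and 0.5884). Under an exchange the arrays labelled ERBB2 would be the untreated control of the EGF arrays. All 32 cell cycle genes, higher in the arrays labelled ERBB2 by a median of 1.42, would then have fallen in 2 h of EGF. KRT15 (log2 difference -3.54) would have risen. Among immediate early genes 11 of 23 would have risen and 2 fallen. Whether 2 h of EGF can do this was not tested.

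Some control probe sets, which lie outside the comparisons of genes, read higher in the arrays labelled ERBB2 than in the vector arrays. The ratios to vector were 3.724 for the 3' and 4.756 for the middle 18S control, 1.933 for the middle 28S control and 1.944 for the ACTB 5'/3' ratio, but 1.192 for the 5' control of 18S and 1.043 for that of 28S; the rises of the first 3 and of the ACTB 5' signal kept their sign with quantile normalization and equal array medians, under which the 5' controls of 18S and 28S were not tested. The bioB spike had a ratio of 1.062. It cannot decide on a uniformly brighter hybridisation, since scaling to the same trimmed mean on all arrays would divide that out. A loss of 5' ends in the vector arrays was not seen for GAPDH, whose 5'/3' quotient was 1.026. That is 1 transcript, and for ACTB the ratio to vector was 2.133 at the 5' end and 1.093 at the 3' end. The 18S control rose least at its 5' end, the reverse of what such a loss would give. GAPDH and 18S thus argue against a loss common to these transcripts. A loss limited to some, as the ACTB values would allow, stays open. A labelling difference might still accompany the rise of the cell cycle genes. Of 32 other probe sets of those genes 84.38% were called up with their gene's main probe set, but the control difference runs with the groups, so the 2 cannot be told apart. No biological explanation of the control signals was tested.

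The splits of the 6 arrays of each pair of groups number 10, too few for a share under 0.05. The real split gave the highest count in each case, 1 of 10 splits. For ERBB2 against vector it called 12689 probe sets and 13 lists, and the highest other split 0 and 6. For EGF against vector the values were 9445 and 13, against 0 and 7, and for ERBB2 against EGF 7792 and 7, against 0 and 5. At an unadjusted limma p under 0.05 the highest other splits gave 1110, 1010 and 1223 probe sets. Mixed splits put real group differences into the spread, so few calls are to be expected there. For the probe sets called in both comparisons with vector, 1 of 100 splits of the 9 arrays, the real one, reached 6961. The highest other gave 4218. This makes a chance assignment of arrays to groups unlikely for that count, provided that the replicates are independent, which the labels do not settle.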

How the results depend on the processing

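The counts of probe sets called in each comparison and in both stayed within 1.5 times of their values under the alternatives except with 1 probe set per gene, which tests fewer features: 6459 against 12689 for ERBB2 against vector, 5208 against 9445 for EGF against vector, 4173 against 7792 for ERBB2 against EGF, and 3970 against 6961 called in both. With each array left out the same counts ranged from 11339 to 12614, 7717 to 9733, 6229 to 7853 and 5764 to 6830. Equal array medians moved the share of rises from 44.8% to 67.5% for EGF against vector and from 48.8% to 31.8% for ERBB2 against EGF; the authors' scaling thus sets the balance of small changes. The falls with EGF numbered 2885 with equal array medians against 5211. Of 9445 calls for EGF against vector, 7119 were shared with equal array medians, none with the opposite sign.

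Lists called numbered 13, 13 and 7 in the 3 comparisons, 6, 6 and 3 with an estimated correlation and 20, 20 and 18 with fry, which tests movement in 1 direction without comparing a list with other genes. Over all alternatives, 694 of 726 values of called lists kept their call, 32 lost it, 18 of these with an estimated correlation, and the direction of the test turned in 0. The median of the extracellular protease and adhesion list in ERBB2 against EGF turned from -0.41 to 0.061 without the filter on low values, and the cause was not tested.

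The ERBB2 log2 change of -0.715 was 0.892 and 0.103 with the other ERBB2 probe sets, and ranged from -0.929 to -0.535 with each array left out. Of 6353 values of genes under the rule, 6254 stayed, 80 lost and 13 gained a call, and 6 turned, all uncalled values near 0. EGFR with EGF (0.03) was -0.007 with quantile normalization and between -0.04 and 0.069 with an array left out, ERBB2 in ERBB2 against EGF between -0.206 and 0.112, and CXCR4 there between -0.248 and 0.003; the cause was not tested. 

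Same-numbered arrays deviated with correlations from -0.03 to 0.019, so the numbers are not taken to pair the samples. With the replicate number as a block, 12551, 9312 and 7618 probe sets were called, and the list of delayed early genes had an adjusted p of 0.05259 in ERBB2 against vector, the only list call lost. Without detection calls, signal over background limits the dim probe sets to an unknown degree.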

Other observations

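The symbol families below and their tests were chosen after the data were seen. Among 151 families of at least 10 genes sharing the start of their symbol, those of ribosome assembly and nuclear pores moved together. All 10 UTP genes, of the small subunit processome, rose in the arrays labelled ERBB2 (median log2 change 0.94; camera adjusted p = 2.053e-06, adjusted p = 0.1334 with an estimated correlation) and with EGF (1.0; adjusted p = 1.506e-08, adjusted p = 0.0774 with an estimated correlation). Of 24 nucleoporins (NUP) 19 rose in the arrays labelled ERBB2 and 14 with EGF, and none fell (adjusted p = 8.348e-07 and 0.001024; adjusted p = 0.1334 and 0.4154 with an estimated correlation). Of 49 genes of the large mitochondrial ribosomal subunit (MRPL) 29 rose and 1 fell in the arrays labelled ERBB2 (adjusted p = 8.348e-07, adjusted p = 0.3388 with an estimated correlation). With EGF 21 rose and 3 fell (adjusted p = 0.0004009, adjusted p = 0.5123 with an estimated correlation). Of 14 TIMM genes, of mitochondrial protein import, 12 rose in each comparison (adjusted p = 4.411e-05 and 3.276e-05; adjusted p = 0.1334 and 0.1675 with an estimated correlation). The medians of these 4 families kept their sign in both comparisons with vector under quantile normalization and equal array medians. The 3' control of 18S and the ACTB 5'/3' ratio moved with the arrays labelled ERBB2.

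For genes of the cytosolic ribosome the count of falls depended on the scaling. Of 40 RPL genes 29 fell and 3 rose in the arrays labelled ERBB2 (median -0.32; adjusted p = 0.0003377, adjusted p = 0.6411 with an estimated correlation). With quantile normalization 11 fell and 3 rose (median -0.09), and with equal array medians 26 fell and 3 rose (-0.27). With EGF 22 of 40 fell and 2 rose (-0.19; adjusted p = 0.0217, adjusted p = 0.8279 with an estimated correlation), but 3 fell and 3 rose with quantile normalization (-0.02) and 2 fell and 4 rose with equal array medians (-0.03), so no direction is given for EGF.

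A hypothesis was that the genes moving in opposite directions would hold more of the glycolysis and hypoxia list, since NDRG1 belongs to it; it was written after the changes of the list members had been seen. Of 163 such genes 2 were members, NDRG1 and BNIP3, against 9 of 3609 genes that moved the same way (Fisher's exact test, two-sided p = 0.07902). NDRG1 prompted the hypothesis, and without it 1 of 162 was a member (Fisher's exact test, two-sided p = 0.3557). The first test is void and the other rests on 1 gene, so the hypothesis stays open.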
